A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

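Total RNA from budding yeast labelled BY4743 was measured on 6 single-colour Affymetrix arrays, each holding probe sets for Saccharomyces cerevisiae and for a second yeast species. Per the labels' protocols, cells grew in rich YPD medium with 0.01% of the detergent SDS at 25 °C for 2 days. RNA of 3 samples was isolated with the FastRNA Pro Red kit and served as the control. The other 3 samples were first incubated with zymolyase, an enzyme preparation that digests the glucan of the yeast cell wall, for 20 min at 25 °C, and their RNA was isolated with the MagExtractor kit. Enzyme and kit therefore changed together, and every difference given is that of the enzyme and the kit combined. Per the labels' protocols, about 4 µg of RNA per sample was turned into biotinylated cRNA with the One-Cycle procedure.

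The deposited values are MAS5 signal intensity on a linear scale, per the submitters' processing notes. The MAS5 version, its settings and any detection calls were not given in the sources used here. In the values themselves, the mean signal of all probe sets after trimming 2% at each end lay between 500.2 and 500.3 on every array, so the arrays had been scaled to a common mean. No centring by gene and no reference channel was present. The table held 10928 probe sets and 7 zeros, none of the 7 in an S. cerevisiae probe set, and zeros were set to 0.1 before logarithms were taken.

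Gene names came from the platform annotation, updated through gene identifiers in the NCBI table of assembly R64, which changed 12 symbols. A single gene symbol was given for 7244 probe sets, several genes for 1, and none for 3683, of which 213 were array controls. Of those with a single symbol, 5498 matched an S. cerevisiae gene and 1746 belonged to the other species. The test used 5449 genes. For the 47 genes with several probe sets, the one with the highest mean log2 signal was used. All probe sets passed in the same direction for 4 of the 47 genes, none passed for 29, some passed and others did not for 14, and none of the 47 had calls in both directions. Some yeast genes have near-identical copies, and a probe set shared by copies measures their sum: a probe set shared by RPL18B changed by -0.13 on the log2 scale, and another one of the same gene by -2.95.

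Differences were fitted on log2 signal with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 changes are zymolyase with MagExtractor minus control with Pro Red, with the moderated standard error (SE). Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and an exact permutation test of 3 against 3 cannot give a two-sided p under 0.1. No pair of arrays shared more than 0.202% identical gene signals.

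Before the data were examined, 35 gene lists were fixed to cover cell wall, stress, growth, metabolism and the cell types a culture could hold. The 33 lists with at least 5 genes measured were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The list of mitochondrially encoded genes had 0 genes measured, and that of short non-coding RNAs had 1, with a log2 change of 0.08. Genes to be named were also set before the data were examined. They were the 12 largest rises and 12 largest falls among genes past the threshold with a change of at least 2-fold, groups that did not overlap, and a mean in the higher group above the median gene. From each list past its test, up to 4 members in the list's direction and up to 2 against it were added, and from each other list the member with the smallest p. The 5 auxotrophy genes of the strain label and 9 wall, stress and reference genes were named whatever their result. Other genes are named where stated to have been chosen after their values were seen.

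Background was to be read from genes absent from the labelled strain. These genes were bright, so that reference was void, and the 95th percentile of the other species' probe sets was used in its place, which was 8.3 to 10.9 by array. On each array 97.9% to 98.7% of the genes lay above it. Gene lengths from the R64 table are called coding length, because 97.0% of protein-coding ones were multiples of 3. All 5449 genes had a length.

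Samples of both groups carry the numbers 1 to 3 in the labels. Deviations from the group means correlated across genes at 0.49, 0.20 and 0.41 for the same-numbered arrays, each over 0.1, so the numbers were taken to pair the samples, on the evidence of the data and not of the labels' wording. Control array 2 with zymolyase array 3 (0.23) and control array 3 with zymolyase array 2 (0.20) correlated as much as the arrays numbered 2. The arrays numbered 1 stood apart from the others, at -0.70 to -0.75 within groups and on the second principal component, with 21.5% of the variance, so arrays 2 and 3 are not told apart by these values. The fit without the pairing was fixed as the main one and the fit with the number as a block as an alternative. Other alternatives were another pseudocount (16), quantile normalization, median centring, removal of dim probe sets, no intensity trend, each array left out, and other choices of probe sets. After the data were seen, removal of a loess trend with coding length, alone and with the block, and omission of the arrays numbered 1 were added. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

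The procedure was tested on simulated arrays with the means and spreads of the 5449 genes, of which 200 were changed. It recovered 57% of those changed 2-fold and 87% of those changed 4-fold, with the right sign in 100% of those recovered, and called 5 unchanged genes. On the real arrays far more genes, 2316, were called, so these shares do not give the recovery there. A simulated fall of 0.5 in the respiration list was called, and 0 other lists were. That 0 gives no rate of false list calls for the real arrays. There, splits into groups of 3 that mix control and zymolyase arrays called 3 to 13 lists at the preset correlation. Those splits keep part of the difference between control and zymolyase arrays, so their counts give no such rate either.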

Results

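Expression of 5449 yeast genes was compared between 3 arrays of cells treated with zymolyase and extracted with the MagExtractor kit, and 3 control arrays of untreated cells extracted with the FastRNA Pro Red kit. The series was set up to record the expression response to zymolyase, and its design text also names the comparison of RNA extraction methods. The median gene had a signal of 552.0 to 600.8 on the control arrays and 629.7 to 677.6 on the zymolyase arrays. The log2 signals of arrays of the same group correlated at 0.953 to 0.985 across genes, and those of different groups at 0.875 to 0.932.

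The strain label was examined first. BY4743 is a diploid laboratory strain of both mating types. Its genotype in the labels lists deletions of HIS3, LEU2 and URA3, which serve histidine, leucine and uracil synthesis, and of LYS2 and MET15 (MET17), of which BY4743 keeps a functional copy. The transcripts of HIS3, LEU2 and URA3 were bright on all 6 arrays. URA3 had a signal of 1956 ± 61.6 in control and 2648 ± 26.6 in zymolyase arrays, HIS3 1080 ± 147 and 552 ± 107, and LEU2 684 ± 160 and 401 ± 27.3 (mean ± SD, n = 3 each). The lowest of these values on any array was 370.9, against a background of at most 10.9. The HIS3 allele of the label is a partial deletion, so its probe set alone checks nothing, whereas the labelled LEU2 and URA3 alleles remove the coding sequence. LYS2 and MET17 had signals of 750.0 ± 128 and 4002 ± 882 in control and 1061 ± 90.7 and 2028 ± 1426 in zymolyase arrays.

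Mating-type genes, a set chosen after the values were seen, also went against the label. The alpha-specific genes STE3, MF(ALPHA)1, MF(ALPHA)2 and SAG1, for the a-factor receptor, alpha-factor and alpha-agglutinin, had signals of 1485 to 7412, above the median gene on every array. The 7 a-specific genes, among them STE2, MFA1 and BAR1, had signals of 8.0 to 133.8, below it on every array. The 9 genes that an a/alpha diploid represses, among them HO, RME1 and GPA1, had signals of 282.0 to 2587. All 9 lay above the background on every array. Against the median gene they did not part clearly, with 3 above it on every array and all 9 above it on at least 1 array. HO had a signal of 330.1 ± 52.3 in control and 1295 ± 424 in zymolyase arrays, and RME1 of 1938 ± 66.8 and 954.6 ± 140 (mean ± SD, n = 3). Signals of different probe sets are not on a common scale. Alpha-specific genes were bright and a-specific genes dim in both groups, so the samples are referred to as labelled BY4743.

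**Figure D1:**
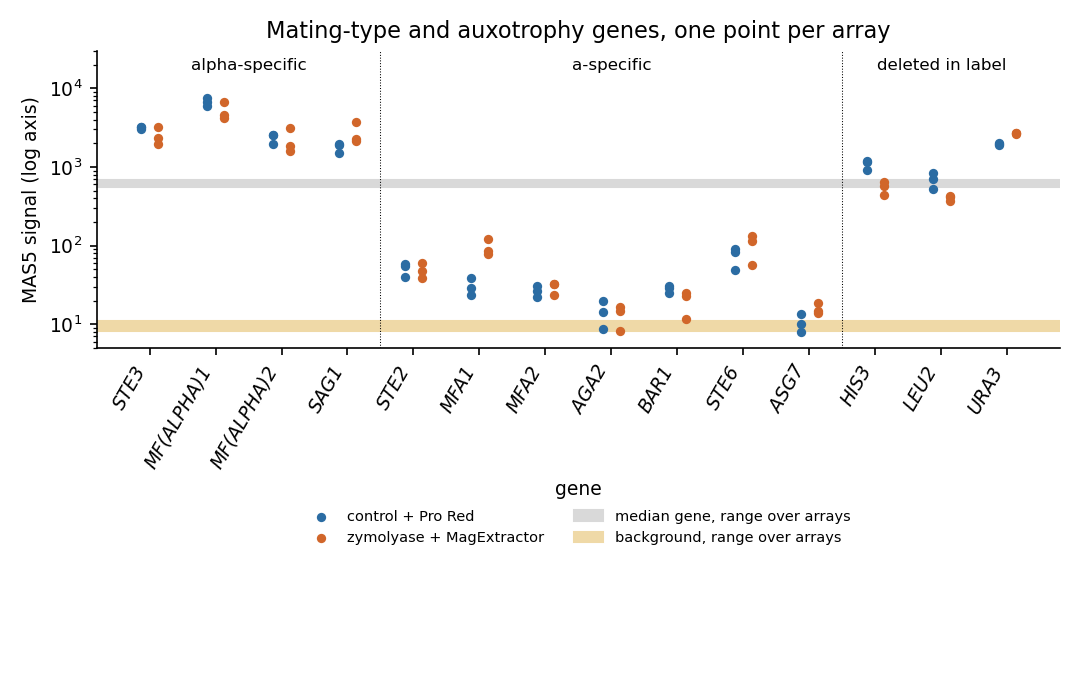
MAS5 signal on a log axis of 4 alpha-specific genes, 7 a-specific genes and 3 genes deleted in the labelled strain, with 1 point per array. The alpha-specific genes lie at 1485 to 7412, the a-specific genes at 8.0 to 133.8 and HIS3, LEU2 and URA3 at 370.9 or above. The bands are the range over arrays of the median gene and of the background, which is 8.3 to 10.9.

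Between zymolyase with MagExtractor and control with Pro Red, 1224 genes were higher and 1092 lower. Of 85 genes for making ribosomes 36 rose and 47 did not pass, and of 45 genes of respiration 24 fell and 21 did not pass. Neither list call held with an estimated correlation (camera adjusted p = 0.961 for both), and the 3′/5′ signal ratio of control genes differed on the same arrays by 1.74 (log2). Of the genes past the threshold, 535 were at least 2-fold higher and 466 at least 2-fold lower. The 3 values of one group lay apart from the 3 of the other in 52.9% of genes, where chance gives 10%. The median log2 change of all genes was 0.04 on the deposited scaling. Centring each array on its median lowered every change by 0.16, after which 951 genes were higher and 1463 lower, or 39.4% of calls higher in place of 52.8%. No gene called on the deposited scaling changed sign under median centring, quantile normalization or the other pseudocount.

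The transcripts of the array's own control genes were lower toward their 5′ end in the zymolyase arrays. The signal of the 3′ probe set over that of the 5′ probe set, averaged over 8 yeast genes, was 1.49 to 1.99 in control and 4.57 to 7.21 in zymolyase arrays. Its log2 was 0.85 ± 0.24 and 2.60 ± 0.35 (mean ± SD, n = 3), a difference of 1.74 with SE 0.25 (exact two-sided permutation p = 0.1, the smallest possible). The ratio was higher in zymolyase arrays for all 8 genes. ACT1, for actin, changed by -2.21 at its 5′ probe set, by -1.50 in the middle and by -0.11 at its 3′ probe set. For 4 bacterial transcripts with poly-A tails that serve as labelling controls, the same log2 ratio was 0.80 ± 0.13 and 0.67 ± 0.24 (SD, n = 3, exact permutation p = 0.4).

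**Figure D2:**
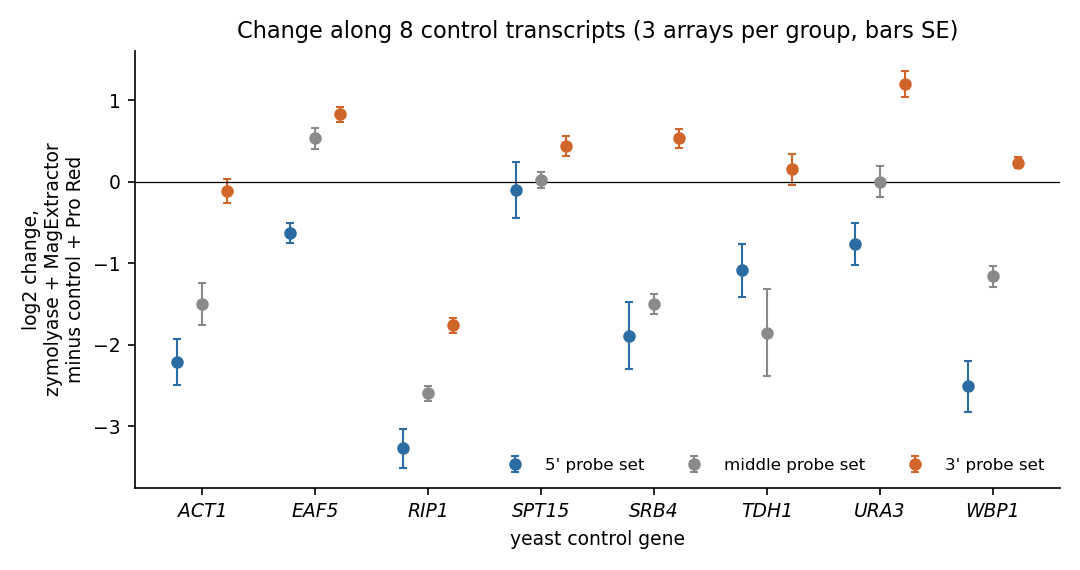
Log2 change from control to zymolyase arrays, with SE (3 arrays per group), of the 5′, middle and 3′ probe sets of 8 yeast control genes. The 3′ probe set lies above the 5′ probe set in all 8 genes, and RIP1 lies below 0 at all 3 positions (-3.27, -2.59 and -1.76).

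The change also rose with coding length. Across genes, which are not independent replicates, Spearman's rho between the change and coding length was 0.34, and 0.32, 0.31 and 0.34 in the 3 pairs of same-numbered arrays. The median change was -0.33 in the second shortest of 10 equal classes of genes by length, with a median length of 564 bases, and 0.60 in the longest class, with a median of 3531 bases. In the longest class 53.4% of genes rose and 4.04% fell. With the length trend removed, an alternative added after the data were seen, 1003 genes were higher and 1050 lower, and 1676 of the 2316 called genes kept their call, all in the same direction.

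**Figure D3:**
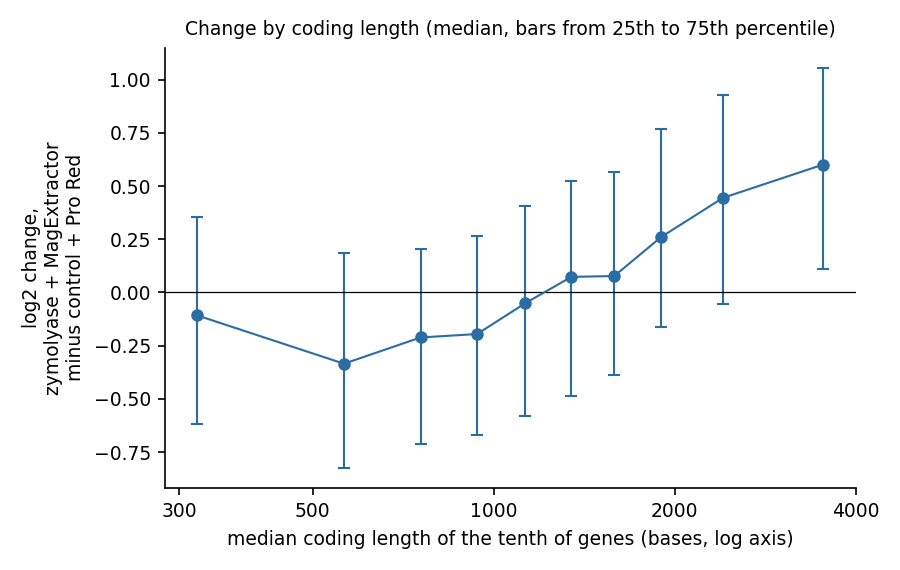
Median log2 change, with bars from the 25th to the 75th percentile, of genes in 10 equal classes of coding length (log axis, bases). The medians run from -0.33 in the second class to 0.60 in the longest.

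Among genes that met the criteria for naming, which include a mean in the higher group above the median gene, the largest rises were spread over several functions. JJJ1, a co-chaperone of the large ribosomal subunit's assembly, rose 5.05-fold (log2 2.34, SE 0.33), BUD22, needed for small-subunit assembly, 5.03-fold (2.33, SE 0.33), and HCA4, an rRNA-processing helicase, 4.98-fold (2.32, SE 0.37). RPC53, a subunit of RNA polymerase III, rose 4.75-fold (2.25, SE 0.26) and IOC2, of a chromatin-remodelling complex, 4.95-fold (2.31, SE 0.32). HFA1, the mitochondrial acetyl-CoA carboxylase, rose 5.24-fold from 436 ± 62.8 to 2301 ± 476, TRK2, a potassium transporter, 5.05-fold from 155 ± 22.1 to 791 ± 155, and KEX1, a protease that processes alpha-factor, 4.83-fold from 667 ± 240 to 3361 ± 1589 (mean ± SD, n = 3). With the length trend removed the log2 change of HFA1, a gene of 6372 bases, went from 2.39 to 1.63. The largest rise was that of YLL066W-B, a subtelomeric reading frame read by a probe set that copies can share, at 9.58-fold (3.26, SE 0.47). Its other probe sets were dim and changed by 2.62 (mean signal from 28.7 to 194.1) and 1.57 (from 13.3 to 39.0). The background was at most 10.9. YCL021W-A and YMR030W-A, of unknown function, rose 7.73-fold and 5.30-fold. YHL009W-B, of a Ty retrotransposon and read by a probe set that copies can share, rose 5.13-fold, with adjusted p = 0.0216 (6.54e-08 to 0.0868 over the alternatives). Its call was lost without zymolyase array 2 (0.0803) or 3 (0.0634) and with the length trend removed (0.0868). The highest adjusted p of the other large rises was that of KEX1, at 0.00513 (limma).

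The largest falls by the same criteria reached into the membrane, the secretory pathway, translation and the cell cycle. YRO2, a plasma membrane protein related to Hsp30, fell 7.75-fold, from 3269 ± 841 to 429 ± 159 (mean ± SD, n = 3; log2 -2.95, SE 0.29). OST6, of the oligosaccharyltransferase, fell 5.81-fold (-2.54, SE 0.22), and HAC1, the transcription factor of the unfolded protein response, 4.67-fold (-2.22, SE 0.16). SLG1, a sensor of the cell wall integrity pathway, fell 4.76-fold, from 939 ± 123 to 203 ± 65.5. DED1, a helicase of translation initiation, fell 5.34-fold, and the ribosomal protein genes RPS28B and RPL9B 5.59-fold and 4.56-fold. RIP1, the Rieske iron-sulfur protein of the respiratory chain, fell 5.08-fold and CHO1, the phosphatidylserine synthase, 4.77-fold. PDX3, of pyridoxal phosphate synthesis, fell 4.54-fold, CLB2, a mitotic cyclin, 4.52-fold, and COS7, a subtelomeric membrane protein gene read by a shared probe set, 4.94-fold. The highest adjusted p of these 12 falls was that of CHO1, at 0.00523, and none of the 12 lost its call without any single array.

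Ribosome biogenesis genes passed as a list with a preset correlation only. Of 85 measured, 36 rose, 2 fell and 47 did not pass, over all genes as well as adjusted over the list alone, with a median log2 change of 0.73 (camera adjusted p = 2.0e-04, adjusted p = 0.961 with an estimated correlation, and fry adjusted p = 0.205). SPB1, a methyltransferase of the large subunit's assembly, rose 3.92-fold (1.97, SE 0.28), UTP14, of the small-subunit processome, 3.56-fold (1.83, SE 0.27), MAK16 3.49-fold and SSF1 3.43-fold, the last 2 also for the large subunit. The list's adjusted p ranged from 8.96e-10 to 0.0283 over the alternatives at the preset correlation. At that preset 9 of the 10 splits of the arrays into groups of 3, the real one included, called 4 lists or more. Each of the other splits keeps part of the difference between control and zymolyase arrays, so they give no rate of false list calls. Every list call at the preset correlation, here and below, was lost with an estimated correlation. Against the list, TIF6 fell 1.77-fold (log2 -0.82, and -0.53 with the length trend removed) and IMP3 3.02-fold (adjusted p = 0.0309, and 7.57e-07 to 0.112 over the alternatives). The fall of IMP3 was lost without control array 1 (0.0519) or 3 (0.0608), without zymolyase array 2 (0.112) or 3 (0.0972), and with the length trend removed (0.0760). The list had a median coding length of 1605 bases, against 1236 for all genes, and its median change was 0.56 with the length trend removed (camera adjusted p = 0.000439). The 3′/5′ ratio of the control genes was higher on the same arrays, by 1.74 on the log2 scale.

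Of 45 genes of the tricarboxylic acid cycle and respiration, 24 fell, 0 rose and 21 did not pass by limma. The counts were 25 and 0 adjusted over the list alone, and at an unadjusted p under 0.05 the counts were 28 and 0. Their median log2 change was -0.54 (camera adjusted p = 5.9e-06, adjusted p = 0.961 with an estimated correlation, and fry adjusted p = 0.0159). The adjusted p ranged from 7.37e-08 to 0.000556 over the alternatives at the preset correlation. Besides RIP1, the strongest falls were those of COX5A, a cytochrome oxidase subunit, at 3.31-fold (-1.72, SE 0.18), SDH2, of succinate dehydrogenase, at 2.89-fold (-1.53, SE 0.17), and NDI1, the internal NADH dehydrogenase, at 2.84-fold (-1.51, SE 0.27). These genes are short, with a median coding length of 639 bases, and the list's median was -0.51 with the length trend removed (camera adjusted p = 0.000137). The falls stood beside the 3′/5′ difference of 1.74, and RIP1 fell by 1.76 at its 3′ probe set.

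Amino acid biosynthesis genes under Gcn4, the activator of that pathway, fell in greater number than they rose. Of 39 measured, 14 fell and 5 rose, with the same counts adjusted over the list alone. The median log2 change was -0.43 (camera adjusted p = 0.0312, adjusted p = 0.961 with an estimated correlation, and fry adjusted p = 0.0687). HOM2, of threonine and methionine synthesis, fell 3.52-fold, GLN1, the glutamine synthetase, 3.24-fold, ARG1, of arginine synthesis, 3.26-fold, and ILV2, of branched-chain amino acid synthesis, 2.38-fold. Against the list, LYS20 rose 2.35-fold and HIS7 1.86-fold. Without control array 1 the median was -0.25 and the adjusted p 0.0662, the highest of a range from 0.00938 over the alternatives at the preset correlation. The adjusted p of ARG1 and ILV2 reached down to 2.46e-06 and 2.13e-07 over the alternatives. The call of ARG1 was lost without zymolyase array 2 (0.0625), and that of ILV2 without zymolyase array 2 (0.0649) or 3 (0.0573). The median was -0.38 with the length trend removed (camera adjusted p = 0.0106), and the same arrays carried the 3′/5′ difference of 1.74.

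Of 27 general stress genes under Msn2 and Msn4, 8 fell, 0 rose and 19 did not pass by limma, both over all genes and adjusted over the list alone, and 13 and 0 did so at an unadjusted p under 0.05. The median log2 change was -0.50 (camera adjusted p = 0.0309, adjusted p = 0.961 with an estimated correlation, and fry adjusted p = 0.150). MSN4 itself fell 3.12-fold and UBI4, for polyubiquitin, 2.81-fold. DDR2 fell 1.99-fold and HSP26, a small heat shock protein, 1.89-fold. The list's adjusted p was 0.127 without control array 2 and 0.0850 after quantile normalization, in a range from 0.000560 to 0.127 over the alternatives at the preset correlation. The call of DDR2, whose groups overlapped, was lost without control array 2 or 3 or zymolyase array 1 or 2, with adjusted p from 0.0658 to 0.110. That of HSP26 was lost without control array 2 (0.0549) and with the length trend removed (0.0792). The lowest adjusted p over the alternatives were 0.000212 for DDR2 and 0.000379 for HSP26. The median was -0.58 with the length trend removed (camera adjusted p = 0.0106), beside the same 3′/5′ difference of 1.74.

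**Figure D4:**
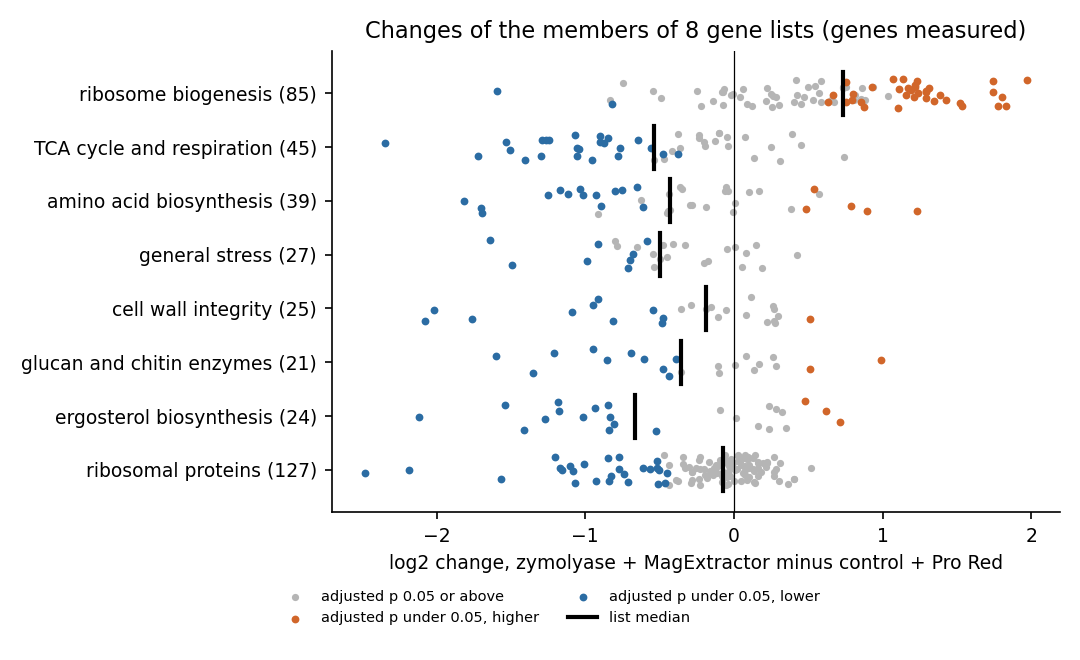
Log2 change of each measured member (points, coloured where the adjusted p was under 0.05) and the median (bar) of 8 gene lists, with the number of genes measured in parentheses. Medians run from -0.67 for ergosterol biosynthesis to 0.73 for ribosome biogenesis, and only the first 4 lists passed the camera test at the preset correlation.

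Cell wall genes did not pass as lists by camera on the deposited values, and passed under several alternatives. Of 25 targets of the cell wall integrity pathway, 10 fell and 1 rose, also adjusted over the list alone, with a median log2 change of -0.19 (camera adjusted p = 0.0832). PIR1, a glucan-linked wall protein, fell 4.06-fold from 3449 ± 715 to 842 ± 112 (n = 3). Of 21 enzymes that make or remodel glucan and chitin, 10 fell and 2 rose, or 11 and 2 adjusted over the list alone (median -0.36, camera adjusted p = 0.0832). KRE9, needed for β-1,6-glucan, fell 3.03-fold. SLT2, the pathway's kinase, and RLM1, its transcription factor, had log2 changes of 0.27 (SE 0.17) and 0.22 (SE 0.15), and the chitinase gene CTS1 -0.24 (SE 0.18), with adjusted p of 0.237, 0.283 and 0.307. RLM1 took the other sign with the length trend removed, at -0.07, and SLT2 ranged from 0.11 to 0.41 over the alternatives. CTS1 passed with 2 arrays per group (-0.46, adjusted p = 0.0137), within 0.0137 to 0.701 over the alternatives. The glucan synthase genes FKS1 and GSC2 had changes of -0.36 (SE 0.13, adjusted p = 0.0567) and 0.26 (SE 0.12, adjusted p = 0.120), and with the replicate block their adjusted p was 0.0232 and 0.0348. With the length trend removed FKS1 changed by -1.08, and GSC2 took the other sign, at -0.47. Over the alternatives the adjusted p of FKS1 ranged from 0.000624 to 0.159 and that of GSC2 from 0.00495 to 0.625. The targets of the integrity pathway passed without control array 3 (0.0328) or zymolyase array 2 (0.0445), in a range from 0.0106 to 0.281 over the alternatives at the preset correlation. The glucan and chitin enzymes passed without control array 3 (0.0372), in a range from 0.00967 to 0.198, and by fry (adjusted p = 0.0159). Both lists also passed without the dimmest genes (0.0463 and 0.0413) and with all probe sets other than controls (0.0359 for both). The latter setting adds 1746 probe sets of the other species and 3470 without a gene symbol to the comparison, so it lends the lists no support. With the length trend removed both lists had a median of -0.47, with adjusted p of 0.0106 and 0.00967, and of the 25 pathway targets 12 fell and 0 rose. Neither passed with an estimated correlation (adjusted p = 0.961 for both).

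Of the remaining lists, none passed at the preset correlation. Ergosterol biosynthesis had 13 of 24 genes lower and 3 higher (13 and 4 adjusted over the list alone), with a median of -0.67 and camera adjusted p = 0.0968, which was 0.0488 without zymolyase array 1 (0.0384 to 0.270 over the alternatives at the preset correlation) and 0.961 with an estimated correlation. ERG9, the squalene synthase, fell 2.27-fold. Cytosolic ribosomal protein genes had 26 of 127 lower (19 adjusted over the list alone), a share near that of all genes, with 1092 of 5449 lower. The list had a median of -0.07 and camera adjusted p = 0.0540. That list passed without control array 1 (0.0445) or 3 (median -0.17, 0.000283) or zymolyase array 2 (median -0.14, 0.00159). It also passed by camera with the other pseudocount (0.0494), median centring (0.0312), the dimmest genes removed (0.0212) and 2 arrays per group (0.0371). With the length trend removed its median took the other sign, at 0.17, with adjusted p = 0.620, the highest over the alternatives at the preset correlation, and with an estimated correlation the adjusted p was 0.992. The counts and median of ribosomal protein genes rest on 1 probe set per gene, for some genes one shared by copies. Those used for RPS8A and RPS23A changed by 0.09 and 0.03, and the other ones by -0.81 and -0.82. For RPL2A the one used changed by -0.03 and the other by 0.32. INO1, for inositol synthesis, fell 3.91-fold, RTA1, a drug efflux target, 4.09-fold, and MET13, of methionine synthesis, 4.70-fold. HXT1, a low-affinity glucose transporter, rose 5.85-fold from 95.4 ± 68.0 to 471 ± 99.0 (n = 3), POL1, the DNA polymerase alpha subunit, 2.61-fold and SSE1, an Hsp70-family chaperone, 1.70-fold. With the length trend removed the log2 change of POL1 went from 1.38 to 0.73, and the call of SSE1 was lost (0.0754, the highest over the alternatives, from 0.000768). The list of haploid-specific and mating genes had 8 of 26 higher and 2 lower (camera adjusted p = 0.328), with FUS2, of cell fusion, rising 3.19-fold, and that of meiosis and sporulation had 2 of 25 higher and 4 lower (camera adjusted p = 0.986).

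Of the reference genes, ACT1 had a log2 change of -0.12 (SE 0.16) and TDH3, the main glyceraldehyde-3-phosphate dehydrogenase, 0.23 (SE 0.18), with adjusted p of 0.577 and 0.349. ACT1 took the other sign under some alternatives, which spanned -0.28 to 0.03, and TDH3 passed without control array 2 (log2 change 0.42, adjusted p = 0.0487, within 0.0211 to 0.832 over the alternatives). HSP12, a stress-induced membrane protein gene, had -0.33 (SE 0.20, adjusted p = 0.220), and -0.53 without control array 1 (adjusted p = 0.0491, within 0.0491 to 0.556 and -0.53 to -0.15 over the alternatives). GPD1, of glycerol synthesis, fell 1.59-fold (adjusted p = 0.0128), a call lost without control array 2 (0.0539, the highest over the alternatives, from 0.00178). MET17 had a log2 change of -1.18 (adjusted p = 0.0558), which passed with the replicate block (0.00474) and without zymolyase array 1 (-1.71, adjusted p = 0.00118), within 2.08e-07 to 0.184 over the alternatives.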

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

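All tests of explanations in this part were chosen only after the results were seen.

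The ratio of 3′ to 5′ signal of the yeast control genes, which no gene test used, differed between the groups by 1.74 on the log2 scale, more than the spread of either group. A labelling reaction that stopped early on the zymolyase arrays was argued against, because the same ratio changed by -0.12 (SE 0.16) in the 4 bacterial poly-A transcripts added for labelling, and by -0.24 without zymolyase array 1, -0.05 without control array 1 and 0.00 without zymolyase array 3. The middle probe set lay between the 5′ and 3′ ones in 7 of 8 genes, all but TDH1. Any loss toward the 5′ end gives that order, so breakdown of yeast RNA before labelling stays open. The zymolyase incubation and the RNA kit cannot be told apart, nor a response of the cells from either, since 0 arrays carried only one of them.

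The 3′ probe set of 25S ribosomal RNA changed by 1.22 on the log2 scale (SE 0.60, exact permutation p = 0.1), or 0.66 without control array 1, and the 5′ one by -3.35 (exact permutation p = 0.1). The middle one changed by -3.73 (exact permutation p = 0.2), outside the range of the ends, and by 0.53, -5.92 and -5.82 in the 3 pairs, between the ends in the first pair only. The 18S probe sets changed by -1.99 (exact permutation p = 0.2), and by 0.61, -3.23 and -3.33 in the pairs. The signal of the 4 poly-A transcripts changed by 1.75 (SE 1.23, exact permutation p = 0.3), by 2.71 without zymolyase array 1 and by 1.03 without control array 1. Of 3470 probe sets without a gene symbol, 220 were above background on every array, and among these 34 were higher and 50 lower in the zymolyase arrays, with the largest changes at 2.96 (SE 0.46) and -2.78 (SE 0.37).

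A trend with coding length as the whole cause was argued against for the respiration list. Its median over the 3 pairs of same-numbered arrays was -0.47 (SD 0.14) with the trend removed. In amino acid biosynthesis the trend took up 0.02 (SD 0.11), beside a mean change of -0.36. That list's median coding length, 1287 bases against 1236 for all genes, left the trend little to take up. Its median of -0.39 (SD 0.16) after removal therefore adds no support. Ribosome biogenesis (0.55, SD 0.32) and general stress (-0.57, SD 0.44) missed the first criterion, a mean beyond 2 SD of 0, and a second was chosen after that. By it the trend took up 0.15 (SD 0.07) of a mean change of 0.71 in ribosome biogenesis. In general stress it took up 0.11 (SD 0.12), in the other direction, against -0.46. A criterion chosen after another was missed cannot decide the question, so the trend as the whole cause stays undecided for ribosome biogenesis. For general stress the part that the trend took up was a rise in all 3 pairs (0.04, 0.25 and 0.05), while the list fell. These values argue against the trend as the whole cause of that fall. With the trend removed, ribosome biogenesis and general stress passed camera at the preset correlation (adjusted p = 0.000439 and 0.0106). Before removal neither of these lists held with an estimated correlation (0.961 for both). Probe positions along transcripts were not used here, so an effect of position beyond coding length stays open for all 4 lists, beside a response to zymolyase.

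For the bright HIS3, LEU2 and URA3 transcripts, background signal was argued against, since their lowest signal was 370.9, against a background of at most 10.9. A culture of another mating type and genotype than labelled was in line with all 4 alpha-specific genes lying above the median gene on every array, and none of the a-specific genes, although different probe sets share no common scale. Labelled cells mixed with other cells stay open: the a-specific genes had a geometric mean of 30.0, and a bulk signal gives no genotype per cell. Whether the culture or the label was exchanged was not tested, and bright alpha-specific and dim a-specific genes were common to both groups.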

How the results depend on the processing

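Removal of the length trend, alone and with the replicate block, and omission of the arrays numbered 1 were chosen after seeing the data, as was the background from the other species. The counts of genes higher and lower stayed within 1.5 times under every alternative, and every gene called in both settings kept its direction. Without each array in turn, the genes past the threshold, higher after zymolyase, numbered 851 to 1350. The genes past the threshold, lower after zymolyase, numbered 740 to 1175. The genes past the threshold with at least a 2-fold change, higher after zymolyase, numbered 439 to 652, and the genes past the threshold with at least a 2-fold change, lower after zymolyase, 355 to 571. Without the dimmest genes the last count was 310, as fewer genes were tested. The number of lists past the threshold, 4, was 9 without the dimmest genes and 0 with an estimated correlation. The correlation estimated from these arrays was 0.71 for ribosome biogenesis, 0.33 for general stress, 0.20 for respiration and 0.13 for amino acid biosynthesis. The preset was 0.01. With all probe sets other than controls 11 lists passed, but that setting adds the other species' probe sets and those without a gene symbol to the comparison. By fry, 2 lists passed, respiration and the glucan and chitin enzymes. By camera the number was 10 with the length trend removed, 10 with that and the replicate block, and 8 with 2 arrays per group. Without each array in turn it ranged from 3 without control array 2 to 9 without control array 3. The cause of these different list counts was not tested. With the replicate block 1702 genes were higher and 1490 lower, all 2316 called genes kept their call and 876 were added. The block brought FKS1, GSC2 and MET17 past the threshold and changed no other call of a named gene or list, with 4 lists past. LYS2 took the other sign with the length trend removed, at -0.13 with and without the block. The background level from the deleted marker genes was 2302 as their highest mean, 815.7 as their median, and 9.44 when taken from the other species, since the deleted genes were bright. Median centring changed the sign of the medians of heat shock, unfolded protein response, drug efflux and phosphate lists, and quantile normalization that of histones, none of which had passed.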

Other observations

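The tests of explanations in this part, and the genes named in it beyond the naming rule, were chosen only after the results were seen.

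Several groups held strong members without passing as lists by camera, of which the glucan and chitin enzymes passed by fry. Among wall genes, PIR3 and PST1, cell wall proteins, fell by 2.08 and 1.76 on the log2 scale, and KRE6 and CHS2, of glucan and chitin synthesis, fell by 1.21 and 1.35. In the sterol pathway ERG13, the HMG-CoA synthase, fell by 2.12 and ERG27 by 1.54. In the unfolded protein response list 4 of 19 genes rose and 6 fell: HRD3, of endoplasmic reticulum-associated degradation, rose by 1.15 (0.73 with the length trend removed), while DER1 of the same process fell by 1.62. RAD27 and SMC1, of DNA replication and sister chromatid cohesion, rose by 1.56 and 1.28, the latter by 0.69 with the length trend removed. Of mating genes, HO, FUS1, MFA1 and FUS3 rose by 1.93, 1.72, 1.66 and 1.21, MFA1 from a signal of 30.3 to 95.9, below the median gene in both groups. RME1 of the same list fell by 1.03, one of 2 falls beside 8 rises.

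The smallest p of the other lists that did not pass belonged to genes of varied function. RPN7 of the proteasome, MRP21 of the mitochondrial ribosome, PFK2 of glycolysis, MDH2 of gluconeogenesis, PRB1 of the vacuole, GPP2 of glycerol synthesis, GRX2 of oxidative defence and the wall protein gene TIR2 had log2 changes of -1.36, -1.50, -1.20, -1.11, -1.17, -1.01, -0.96 and -1.37. PHO81 of phosphate signalling, CCC2 of copper transport, HHO1 for histone H1, RED1 of meiosis and the trehalase gene NTH2 had 1.27, 1.29, 1.06, 1.23 and 0.84. With the length trend removed PHO81, CCC2 and RED1 kept their calls, with log2 changes of 0.69, 0.77 and 0.81, and NTH2 had 0.46. The call of NTH2 was lost without zymolyase array 2 (0.0690) or 3 (0.0664) and with the length trend removed (0.164), and that of GRX2 with the length trend removed (0.0634). Their lowest adjusted p over the alternatives were 6.82e-05 and 2.94e-05.

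In the COS family of subtelomeric membrane proteins, 5 of 8 measured members fell and 0 rose, with a median of -0.94 and medians of -1.13, -1.09 and -1.19 in the pairs. A fall of the family together stayed undecided, since the mark, set after the values were seen, was 6 falls. Some of its probe sets are shared between members.

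Grouping by chance was examined with the 10 splits of the 6 arrays into groups of 3, which are too few for a share under 0.05. For genes past the threshold, 1 split, the real one, had a count as large, at 2316 against a highest other of 0 by limma, and for 2-fold changes 1 split did, at 1001 against 0. The other splits mix control and zymolyase arrays in each group, which puts the difference between them into the spread. A count of 0 there is therefore no measure of calls by chance. At an unadjusted p under 0.05 the other splits held 1 to 361 genes, against 2794. For lists 9 of the 10 splits gave as many or more, with 4 in the real split and 13 in the highest other. These list counts are no measure of calls by chance either. The groups of each other split hold unequal numbers of control and zymolyase arrays and so keep part of the real difference. The other splits that part all 3 pairs gave 9, 3 and 12 lists with 1, 9 and 41 genes at an unadjusted p under 0.05. The splits that kept the arrays numbered 1 together gave 7, 11, 13 and 13 lists, and the other splits besides the real one 8, 9, 3, 10 and 12, so these ranges overlapped. At an unadjusted p under 0.05 the former held 157 to 361 genes and the latter 1 to 62.

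Kit and enzyme effects on short and long transcripts could be separated only with arrays that carry one of the factors, of which there were 0, so zymolyase against RNA kit stays open for every gene named.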
